A study of Arabidopsis thaliana with 6 samples.

How the data were processed

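Total RNA of whole fertilised flowers at stage 15 was measured in 3 wild-type and 3 atnaod samples, each on 1 single-colour Agilent array. Per the labels, each sample pooled about 100 flowers of 17 to 20 plants grown at 25 °C under 16 h of light and 8 h of dark, and 200 ng of RNA was labelled with Cy3. Per the file headers, the scanner values of each spot are fluorescence intensity read with Agilent Feature Extraction 10.5.1.1 (version 10.5 per the labels). The processed intensity had its background subtracted and its spatial trend removed within the array, and was not normalized between arrays. The deposited values also hold intensity. Each of their columns was checked to be the median spot signal times 1 constant per array (0.732, 0.841 and 1.61 for wild type 1 to 3, and 1.12, 0.774 and 1.57 for atnaod 1 to 3), on a linear scale with no background subtraction. The column medians were 450.9, 465.7 and 518.9 in wild type and 472.0, 457.2 and 498.4 in atnaod, and the 75th percentiles lay between 2140 and 2144.

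Each array held 45220 spots, of which 43803 were not controls, for 43603 probes. The log2 of the processed intensity was taken and the 75th percentile of the array's probes subtracted. Spots that the scanner software marked as outliers (2 to 35 per array) were left out, and the spots of 1 probe were averaged. A probe was tested where the software marked it as well above background on all arrays of at least 1 genotype, which left 32497 probes. A gene with several tested probes was represented by the probe with the highest mean over the 6 arrays, giving 24458 genes, of which 22007 had a locus code and 2451 were transcripts without 1. Locus codes came from the array's annotation and were matched to TAIR10.1 genes, where 37943 of the 38413 probes with a locus code found their locus. The positions of the probes within their genes and of the T-DNA were not analysed here.

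Genes were compared with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8) by lmFit and eBayes with default settings, two-sided, on 3 against 3 samples. A gene was called where its Benjamini-Hochberg adjusted p over all genes tested was under 0.05. Intervals are 95% intervals from the same fit. For a gene that was not above background on any array of 1 genotype, the fold is a bound from the detection floor of the main setting. The floor was the lowest signal of any probe marked as above background on that array, and a higher measured value was kept. Another background correction can give a smaller fold. The 49 gene lists, written before the data were examined from known members or from words in the gene descriptions, were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested (46 lists), with Benjamini-Hochberg adjustment over lists. In 2 lists no gene description matched, and the seed storage list had no member that passed the signal filter. Camera with an estimated correlation and limma's fry stood beside it. Gene families by symbol stem were tested with a one-sided Fisher exact test, a choice made after the data were seen.

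The tests, lists, rule for named genes and most alternatives were fixed before the data were examined. The rule names AtNAOD, all members of the ornithine and arginine synthesis and polyamine synthesis lists, the 10 largest rises and 10 largest falls among called genes with a symbol whose 3 atnaod values lay on 1 side of the 3 wild-type values, and up to 4 members with the lowest p of each other list. Genes outside this rule are said to be chosen after their values were seen.

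The alternatives were another background correction (normexp, offset 50), quantile normalization, median centring, the deposited values, no filter on dim probes, a filter asking for all 6 arrays, the mean over a gene's probes, a trended and robust prior, array weights, replicate number, slide or scan date as a block, and leaving out each sample in turn. The correction was planned on the mean spot signal, a column not used here, and was run on the median spot signal. Its first fit broke on wild type 1, where 5 spots had a local background of up to 394525 against a median of 34, and called 4 genes. Spots with a background over 10 times the array's median therefore took that median. This change, a fit on the first slide alone, the ornithine list without AtNAOD and keyword lists without members of another kind were chosen after seeing the data.

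Samples 1 and 2 of both genotypes shared 1 slide and scan, and sample 3 of both was on another slide and scan, so that slide and scan date cannot be told apart. The replicate numbers come from the labels, and whether they pair the samples was checked in the data. The deviations of same-number samples from their genotype's mean correlated across genes at 0.190, 0.111 and 0.535 for numbers 1, 2 and 3, and the other combinations lay between -0.354 and 0.215. The values of numbers 1 and 2 lay below the highest of the other combinations. Number 3 is also the pair on the other slide, so a pairing by number beyond the slide is not shown. Genes are not independent replicates, so these correlations carry no p.

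Data were simulated with the measured means and the spreads as fitted by eBayes, with 50 genes changed at each size. In the measured data 1414 genes were called, so recovery there can differ. On the simulated data the gene test recovered 10% of the genes changed by 0.5 on the log2 scale and 96% of those changed by 1. It recovered 100% of those changed by 2 or 4, with 15 false calls among 24407 genes. Without any change it called 0 genes and 0 of 46 lists, with 4.75% of unchanged genes at an unadjusted p under 0.05 in the first simulation. Genes were simulated independently of each other, whereas measured lists held correlated genes (estimated at 0.586 for DNA replication and mitosis). The simulation therefore cannot show how often camera at the preset correlation calls such lists by chance. Saturated spots numbered 0 on every array, spike-in slopes lay between 0.980 and 1.04, and repeated spots varied by 4.23% to 5.50%.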

Results

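Whole fertilised flowers of Arabidopsis thaliana at stage 15 were profiled in wild type and in atnaod, a T-DNA line of AtNAOD (AT4G17830), the gene of N-acetylornithine deacetylase, an enzyme of ornithine synthesis. Each genotype had 3 independent replicates, 1 array each. The 75th percentile of processed intensity was 3007, 2618 and 1318 in wild type 1 to 3 and 1956, 2845 and 1355 in atnaod 1 to 3, and 73.2% to 79.2% of probes were well above background. Across genes, which are not independent replicates, Pearson correlations between arrays were 0.988 to 0.994 within a genotype and 0.980 to 0.988 between genotypes. These ranges overlapped slightly: atnaod 1 correlated at 0.98764 with atnaod 3 and at 0.98802 with wild type 2. The first principal component, with 47.9% of the variance, separated the genotypes. The second, with 24.7%, was lowest in sample 3 of both genotypes, the samples on the second slide. The comparison asked which transcripts of the fertilised flower differed when this step of ornithine synthesis was disrupted. The number of arrays limits the precision of every value.

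At its main probe the AtNAOD transcript fell below detection in the mutant. It stood at 1.69 ± 0.07 (SD, n = 3; log2 intensity minus the array's 75th percentile) in wild type, and was not above background in any of the 3 atnaod samples. That makes it at least 369-fold lower by the detection floor of the main setting. The fitted change was -8.84 (SE 0.115, adjusted p = 4.26e-07), with -8.94 on the first slide and -8.62 on the second. A second AtNAOD probe was above background in all samples and fell by 1.23 on the log2 scale (adjusted p over all probes = 0.0286). Both probes were lower in 3 of 3 atnaod samples. The gene lies on chromosome 4 at 9915813 to 9918243 (TAIR10.1), and where each probe sits relative to the T-DNA is not known.

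Among the other 12 tested genes of ornithine and arginine synthesis 0 were called with limma, and of all 13 members, AtNAOD included, 3 had an unadjusted p under 0.05. Examples were the glutamate N-acetyltransferase gene NAOGACT at -0.27 (95% interval -0.48 to -0.05, adjusted p = 0.126), the regulator GLB1 at -0.29 (-0.55 to -0.03, adjusted p = 0.153) and ornithine transcarbamylase OTC at -0.09 (-0.33 to 0.14). The 13 members together had a median of -0.09 (-0.11 and -0.09 on the 2 slides) and missed the camera threshold (adjusted p = 0.0657). They passed without wild type 2 (adjusted p = 0.00984) or with a trended and robust prior (adjusted p = 0.0359), but the other 12 without AtNAOD did not (adjusted p = 0.0852 and 0.276, and 0.371 in the main setting). Adjusted over the list alone, AtNAOD was again the 1 gene called.

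Polyamine synthesis genes showed no called change. Of the 12 members tested with limma 0 were called, also adjusted over the list alone, and 5 had an unadjusted p under 0.05. The list's median was -0.04 (camera adjusted p = 0.944). The largest values were those of the S-adenosylmethionine decarboxylase genes SAMDC1 at 0.35 (95% interval 0.05 to 0.66, adjusted p = 0.147) and SAMDC2 at 0.30 (0.02 to 0.58), and of BUD2 at -0.29 (-0.54 to -0.05), the spermine synthase gene SPMS at -0.28 (-0.49 to -0.08, adjusted p = 0.103) and SPDS2 at -0.23 (-0.44 to -0.03). The arginine decarboxylase genes ADC1 and ADC2 stood at 0.17 and -0.07. Among 18 genes of polyamine oxidation, conjugation and transport, the copper amine oxidase gene CUAO1 rose by 0.60 (SE 0.133, adjusted p = 0.0491), higher in 3 of 3 atnaod samples (0.49 and 0.82 on the 2 slides). It was no longer called with slide as a block (adjusted p = 0.0503) or with the replicate block (adjusted p = 0.0593). The replicate block called 1 other gene of this list, higher in atnaod. Among 13 genes of arginine catabolism and proline metabolism, the proline synthesis gene P5CS2 rose by 0.40 (SE 0.0869, adjusted p = 0.0474), and its call was lost with the replicate block (adjusted p = 0.0529). In all, CUAO1 lost its call in 13 of 19 alternatives. P5CS2 lost its call in 12 of 19, among them quantile normalization and each fit without 1 sample. CUAO1 and P5CS2 were called also adjusted over their list alone, and neither list passed camera (adjusted p = 0.176 and 0.363; medians 0.07 and 0.03).

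**Figure D1:**
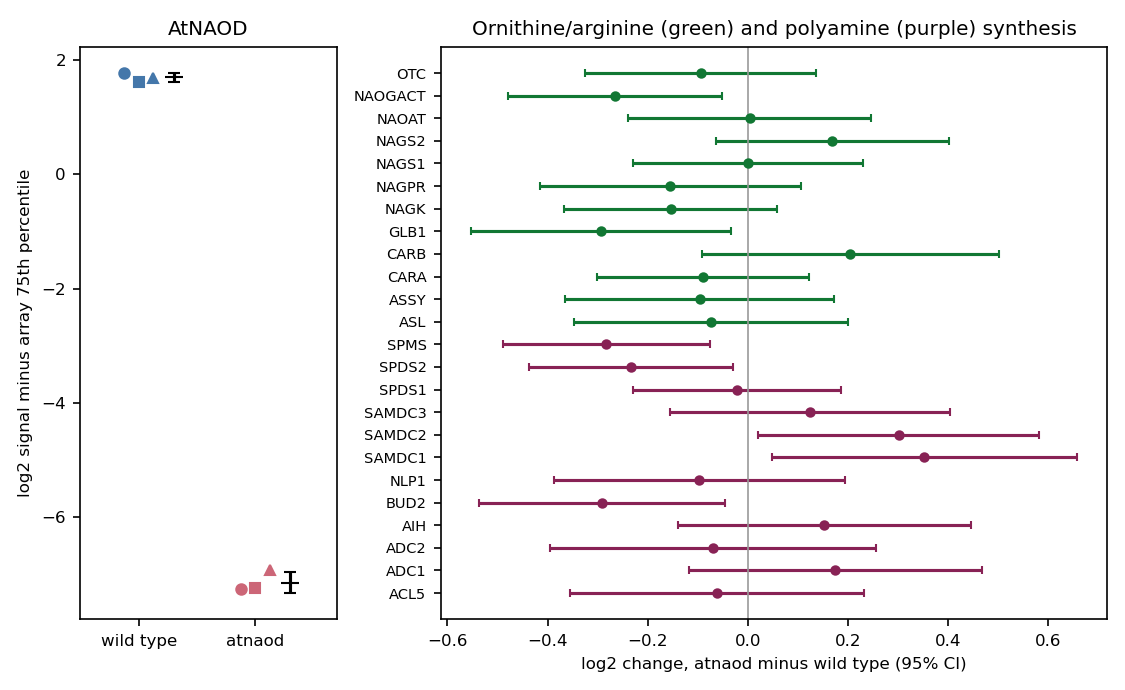
Left, log2 intensity of AtNAOD minus the array's 75th percentile in each sample (circle, square and triangle for replicates 1, 2 and 3), with mean and SD (n = 3). Right, log2 change in atnaod against wild type with 95% interval for the other genes of ornithine and arginine synthesis (green) and polyamine synthesis (purple), none of which was called.

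Across the flower, 1414 of 24458 genes differed, 665 higher and 749 lower in atnaod. Large changes were mostly falls, with 267 genes at least 2-fold lower and 83 at least 2-fold higher, and the median size of a called change was 0.66 on the log2 scale. In 32.3% of all genes tested the 3 atnaod values all lay on 1 side of the 3 wild-type values, where chance gives 10%. So they did in all 1411 called genes with a value on every array, and the other called genes lacked a value. The direction was the same on both slides in 78.5% of all genes and in 100% of these 1411. Both shares among called genes were nearly fixed by the call, which used the same 6 samples, and are no replication. With slide as a block 2123 genes were called (999 higher, 1124 lower). The count depended on single samples: 576 genes were called without wild type 1, 21 without wild type 2, 17 without wild type 3, 15 without atnaod 2 and 139 without atnaod 3, against 1551 without atnaod 1. The number of genes at an unadjusted p under 0.05 moved less, from 6300 with all samples to between 4376 and 6464 in these fits. Of the 110 called genes open to naming, 62, 100 and 101 lost their call without wild type 1, 2 and 3, and 15, 102 and 91 without atnaod 1, 2 and 3. With normexp 79 of the 110 lost their call and 27 changed in size by over 1.5 times, and with the deposited values 104 and 24. The deposited values gave 12 calls, no filter on dim probes 22, the normexp correction 243, a trended and robust prior 2259 and array weights 3977.

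The largest falls among genes with a symbol were led by MRD1 at -6.42 (SE 0.144, adjusted p = 9.48e-06), read by a single probe. Next came genes of small secreted peptides. LCR84, a low-molecular-weight cysteine-rich protein gene, fell by 2.08 (adjusted p = 0.0259), the CLE8 gene of a signalling peptide of the young embryo and endosperm by 2.06 (adjusted p = 0.0283), and SCRL15, of the S-locus cysteine-rich-like family, by 2.02 (adjusted p = 0.0398). LCR35 fell by 1.83 and LCR46 by 1.79. SCRL9, not above background in any atnaod sample, was at least 2.80-fold lower by the floor of the main setting. Its log2 change was smaller and without a call with normexp (-0.50) and with the deposited values (-0.60). The SKP1-like gene SK10 fell by 1.92. ENODL22 and the glucanase gene BG3 both fell by 1.90, with calls lost under the replicate block (adjusted p = 0.0512 and 0.0556).

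The largest rises among genes with a symbol were those of QQS, a gene of carbon and nitrogen allocation, at 2.74 (SE 0.163, adjusted p = 0.00158), and of the transcription factor genes GATA13 at 2.19 (adjusted p = 0.0164) and RAP2.6 at 2.08 (adjusted p = 0.0207). Of transcripts without a symbol, chosen after their values were seen, AY090982 rose by 2.97 (SE 0.135, adjusted p = 0.000422). NP454714, chosen likewise, rose from a level above background in 0 of 3 wild-type samples (adjusted p = 0.00159). The pectin methylesterase gene PME2 rose by 1.72, MLO6 by 1.64, the ATPase gene DAA1 by 1.27 and UGT85A7, above background in 2 of 3 wild-type samples, by 1.39. The glutamate decarboxylase gene GAD5 and the proton pump gene HA9, each above background in 1 of 3 wild-type samples, rose by 1.25 and 1.63. CYP94B3, whose enzyme inactivates jasmonoyl-isoleucine, rose by 1.45, and the calls of HA9 and CYP94B3 were lost under the replicate block (adjusted p = 0.0540 and 0.0606). Of the 20 genes of largest change, 11 were still called without wild type 1, 4 without wild type 2, 3 without wild type 3, 2 without atnaod 2, 9 without atnaod 3 and 19 without atnaod 1. With normexp 11 of the 20 were smaller by over 1.5 times, among them HA9 at 0.62, UGT85A7 at 0.55, GAD5 at 0.33, GATA13 at 1.30, CLE8 at -1.05, SCRL15 at -0.84 and SCRL9 at -0.50, and of these 7 only GATA13 was still called.

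**Figure D2:**
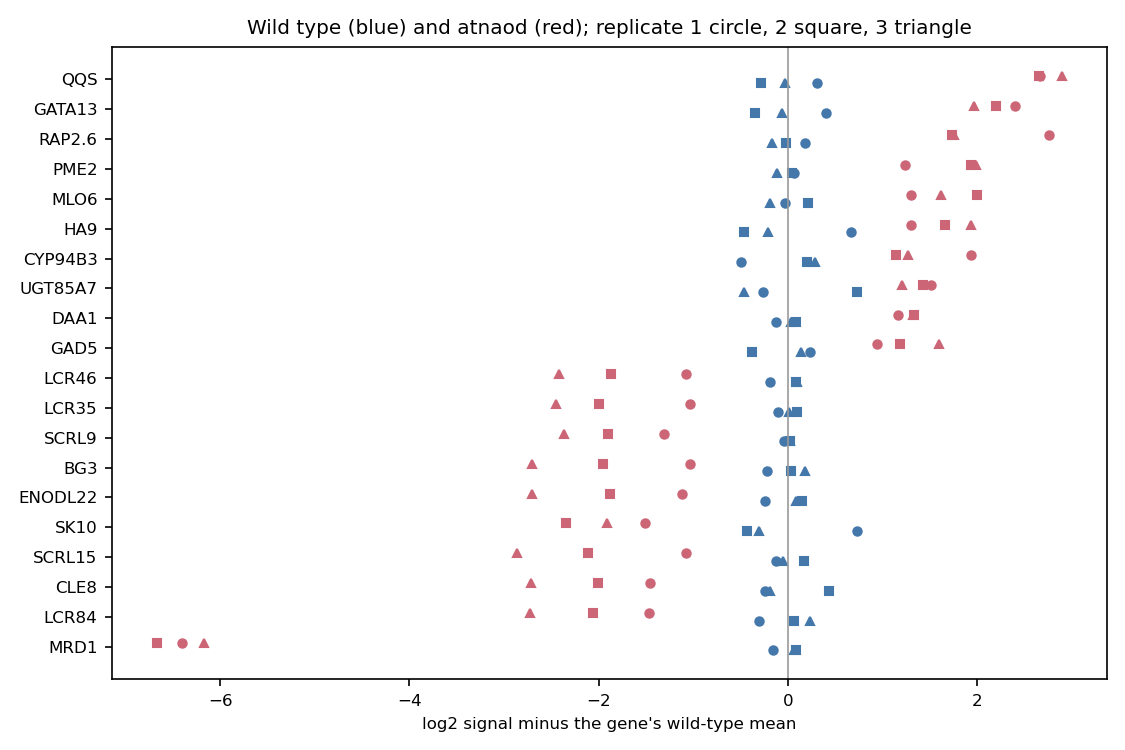
Log2 intensity of each sample minus the gene's wild-type mean for the 10 largest rises and 10 largest falls, wild type in blue and atnaod in red (circle, square and triangle for replicates 1, 2 and 3). MRD1 stands apart at -6.42, and the other falls have mean changes between -2.08 and -1.79.

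Of the 46 gene lists tested, 20 passed the camera threshold with the preset correlation, 10 higher and 10 lower in atnaod, and 26 did not. With an estimated correlation 0 passed (smallest adjusted p = 0.581; 2 lists at an unadjusted p under 0.05), and limma's fry called 2, ribosomal proteins (adjusted p = 0.0477) and ornithine and arginine synthesis (adjusted p = 0.0309, and 0.493 without AtNAOD). Median, mean and test had the same sign in all 20. All 20 also passed with slide as a block and with the replicate block. In 21 of all 46 lists the medians in the 3 atnaod samples all lay on 1 side of those in the 3 wild-type samples, and so they did in 15 of the 20. The exceptions among the 20 were pollen, touch and wounding, lipid transfer, glutathione transferase and MADS-box genes.

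The list of small cysteine-rich secreted proteins, which takes in defensins and the LCR family, was lower as a group. In it 44 genes lay below 0 and 18 above. The LCR family alone held 25 falls in 51 tested members, so a fall of the defensins is not shown. Of 62 tested, 25 fell and 0 rose (32 fell and 3 rose adjusted over the list alone), among them LCR8 at -1.07 (SE 0.146, adjusted p = 0.0221), LCR76 at -1.51, LCR45 at -1.20 and LCR53 at -1.57. The list's median was -0.42 (-0.38 and -0.57 on the 2 slides; adjusted p = 2.40e-06), and adjusted p = 0.605 with an estimated correlation. Its median was below that of every wild-type sample in 3 of 3 atnaod samples.

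Flavonoid genes were lower as a group, and 3 genes of the carpel and ovule fell. Of 20 flavonoid genes 6 fell and 0 rose (9 and 1 adjusted over the list alone): the regulators TT2 at -1.02 (SE 0.149, adjusted p = 0.0257) and TT8 at -0.65, and the enzyme genes LDOX at -1.27 and BAN at -1.06 were the first 4. The list's median was -0.27 (-0.20 and -0.45 on the 2 slides; adjusted p = 0.00139), and adjusted p = 0.656 with an estimated correlation. MYB5 (-0.83) and TTG2 (-0.86), regulators of seed coat development, and GSTF12 (-1.12), whose protein carries flavonoids to the vacuole, fell too. The ovule identity gene STK fell by 0.73 (adjusted p = 0.0283), and SHP1 and SHP2, which act in the carpel, fell by 0.49 and 0.48. These were 3 of 13 tested genes of carpel, ovule and fruit patterning, a list with a median of 0.05 that did not pass (adjusted p = 0.875). CRC stood at 0.59 (adjusted p = 0.0592) and was called with the replicate block (adjusted p = 0.0434).

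Endosperm and early embryo genes had a median of -0.40, with 9 of 11 below 0. The embryo regulator LEC1 fell by 0.68 (SE 0.0998, adjusted p = 0.0259), and AGL28, MINI3 and AGL62 stood at -0.60, -0.83 and -0.35 without a call. Adjusted over the list alone, 3 fell. The list passed camera (adjusted p = 0.0153), and adjusted p = 0.656 with an estimated correlation. Its median was -0.19 on the first slide and -0.72 on the second, and it was no longer past the threshold without atnaod 3 (adjusted p = 0.0977), on the first slide alone (0.146), with normexp (median -0.11, adjusted p = 0.214) or with the deposited values (median -0.15, adjusted p = 0.226). Against the wild-type mean its median was -0.06, -0.53 and -0.58 in atnaod 1, 2 and 3, and -0.04 in wild type 1. MADS-box genes, which share 7 tested genes with the early seed and carpel lists, STK, SHP1 and SHP2 among them, had 6 falls and 1 rise in 52 (10 and 1 adjusted over the list alone), including AGL91 at -1.19 and AGL99, above background in 2 of 3 atnaod samples, at -0.92, while AGL24 rose by 0.64 (list median -0.14, and -0.30 with no filter on dim probes; -0.16 and -0.08 on the 2 slides; adjusted p = 0.00423, and adjusted p = 0.656 with an estimated correlation). Mature pollen markers moved the other way, with a median of 0.28 (0.09 and 0.52 on the 2 slides) and 0 of 27 called with limma, 1 at an unadjusted p under 0.05 (adjusted p = 0.0190, and adjusted p = 0.773 with an estimated correlation). Against the wild-type mean their median was -0.18, 0.27 and 0.60 in atnaod 1, 2 and 3, and the list no longer passed without wild type 1 (adjusted p = 0.0793), without atnaod 3 (median 0.03, adjusted p = 0.533) or on the first slide alone (adjusted p = 0.354). Without atnaod 1 its median was 0.47.

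Genes of cell division and protein synthesis were shifted down by small amounts. In the list of DNA replication and mitosis 27 of 28 genes lay below 0 (median -0.40; -0.33 and -0.54 on the 2 slides), the ribonucleotide reductase gene TSO2 fell by 0.65 (SE 0.124, adjusted p = 0.0371), the 1 gene called against 4 with the replicate block, and 16 fell adjusted over the list alone, with CYCB1;4 at -0.45 and PCNA1 at -0.45. The list gave adjusted p = 4.47e-07, and adjusted p = 0.605 with an estimated correlation. Of 22 histone genes 7 fell (15 fell and 1 rose adjusted over the list alone), among them the H2A genes HTA13 at -0.71 (SE 0.0981, adjusted p = 0.0227), HTA8 at -0.67, HTA2 at -0.52 and HTA7 at -0.47. Their median was -0.35 (-0.32 and -0.46 on the 2 slides; adjusted p = 1.40e-05, and adjusted p = 0.605 with an estimated correlation). Of 66 ribosomal protein genes 64 lay below 0 (median -0.29; -0.26 and -0.35 on the 2 slides), and 7 fell, or 26 adjusted over the list alone, though limma called 0 with the replicate block, where 45 had an unadjusted p under 0.05. RPL24A fell by 0.56 and RPSAb by 0.42 (adjusted p = 0.0605 and 0.0523 with the replicate block). This list had the smallest p of all (adjusted p = 7.17e-13, and adjusted p = 0.581 with an estimated correlation). In all 3 lists the median of each atnaod sample lay below those of the 3 wild-type samples. Against the wild-type mean the cell division medians were -0.25, -0.37 and -0.56 in atnaod 1, 2 and 3, falling as the pollen markers rose. Histone (-0.31, -0.44 and -0.37) and ribosomal medians (-0.22, -0.37 and -0.32) showed no such steady trend. A difference in tissue share was not tested for these lists.

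Heat shock genes were lower, with 21 of 22 below 0 (median -0.32; -0.38 and -0.26 on the 2 slides; adjusted p = 0.000731, and adjusted p = 0.605 with an estimated correlation). The small heat shock protein gene HSP17.8 fell by 0.80 and the ascorbate peroxidase gene APX2 by 1.36, and 2 fell adjusted over the list alone. The list missed the threshold with array weights (adjusted p = 0.0511). Its median was -0.20 without atnaod 1. Of 9 lipid transfer protein genes 2 fell, also over the list alone: LTP fell by 0.54 and LTP5 by 0.70, the latter with adjusted p = 0.0604 under the replicate block (median -0.24; -0.19 and -0.35 on the 2 slides; adjusted p = 0.0141, and adjusted p = 0.656 with an estimated correlation). This list missed the threshold without wild type 3 (adjusted p = 0.0602). Glutathione transferases had 3 falls and 1 rise in 39, also over the list alone (2 and 0 with the replicate block), led by GSTF5 at -1.16, with a median of -0.15 (-0.23 without wild type 1 or with array weights; -0.10 and -0.24 on the 2 slides; adjusted p = 0.0379, and adjusted p = 0.737 with an estimated correlation). They lost the threshold without wild type 2 (adjusted p = 0.173), wild type 3 (0.0869), atnaod 2 (0.162) or atnaod 3 (0.0723), on the first slide alone (0.131), with normexp (0.0638), with the deposited values (0.0658) and with no filter on dim probes (0.117).

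**Figure D3:**
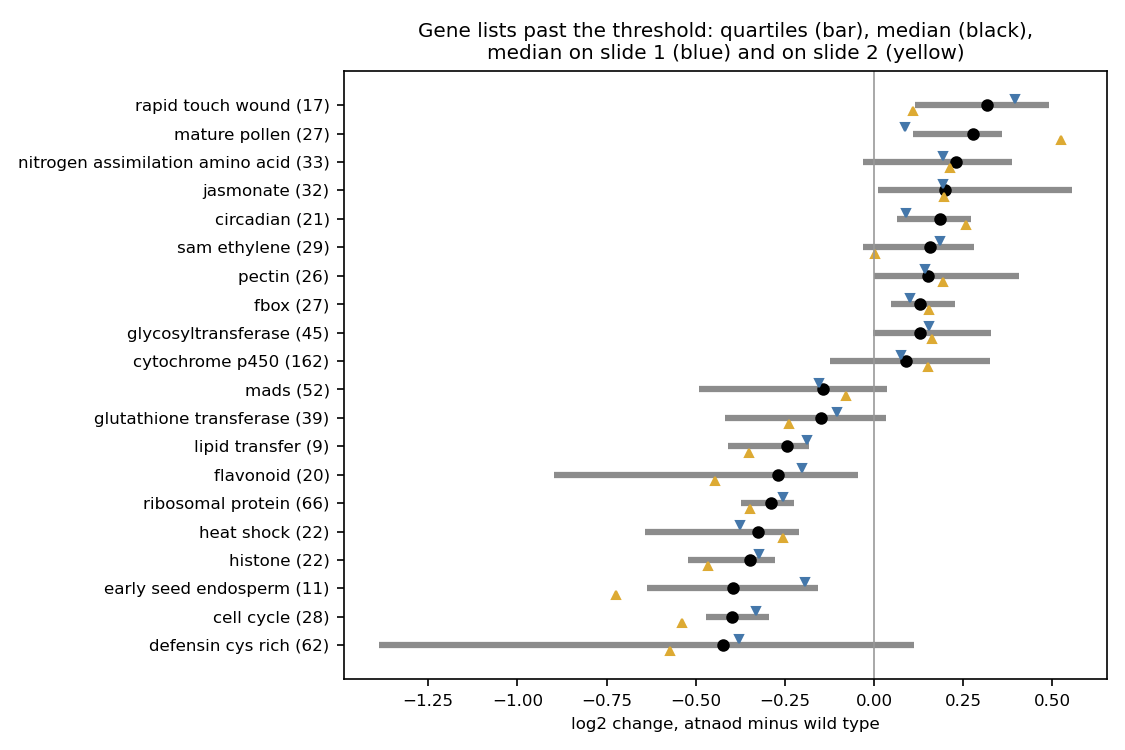
Log2 change in atnaod against wild type of the tested genes in the 20 lists past the camera threshold (number of genes in brackets): quartiles as bars, medians as black points, and medians on the first slide (blue) and second slide (yellow). The medians run from -0.42 for the cysteine-rich proteins to 0.32 for the touch and wound genes, and none of the 20 passed with an estimated correlation.

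Genes of nitrogen assimilation and amino acid metabolism were higher. Of 33 tested 5 rose and 0 fell (7 and 0 adjusted over the list alone), among them GAD5, the nitrate transporter gene NRT1.1 at 0.69 (SE 0.124, adjusted p = 0.0345), the asparagine synthetase gene ASN1 at 0.87 and the glutamate decarboxylase gene GAD2 at 0.50. The list's median was 0.23 (0.19 and 0.21 on the 2 slides), above every wild-type sample in 3 of 3 atnaod samples, with adjusted p = 0.000604, and adjusted p = 0.581 with an estimated correlation.

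Ethylene and jasmonate genes were higher as groups. In the list of the methionine cycle and ethylene, the ethylene-forming oxidase gene ACO3 rose by 1.49 (SE 0.215, adjusted p = 0.0248), and 4 of 29 rose adjusted over the list alone (median 0.16; 0.18 and 0.00 on the 2 slides; adjusted p = 0.0110, and adjusted p = 0.605 with an estimated correlation). Without atnaod 1 this list missed the threshold (median 0.06, adjusted p = 0.145). In the jasmonate list CORI3 rose by 0.87 (adjusted p = 0.0282) and the repressor gene JAZ10 by 0.56, the 2 of 32 called, with 2 adjusted over the list alone, while TAT3 stood at -2.22 without a call (adjusted p = 0.0921; list median 0.20; 0.19 and 0.20 on the 2 slides; adjusted p = 0.00690, and adjusted p = 0.605 with an estimated correlation). The jasmonate list missed the threshold with array weights (adjusted p = 0.0762). The gibberellin receptor genes GID1B and GID1A rose by 0.66 and 0.54 in a list of 26 that did not pass (adjusted p = 0.875).

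UDP-glycosyltransferase and cytochrome P450 genes were higher as groups. Of 45 UDP-glycosyltransferase genes 3 rose and 0 fell (8 and 0 adjusted over the list alone, 5 and 0 with the replicate block), with UGT71C1 at 0.62 (SE 0.0880, adjusted p = 0.0246) and UGT76C2 at 0.43, the latter with adjusted p = 0.0516 under the replicate block (list median 0.13; 0.15 and 0.16 on the 2 slides; adjusted p = 0.000531, and adjusted p = 0.581 with an estimated correlation). Of 162 cytochrome P450 genes 12 rose and 5 fell (19 and 9 adjusted over the list alone, 11 and 8 with the replicate block), with CYP94B1 at 1.16, CYP704A2 at 0.75 and CYP709B1 at -1.03 (list median 0.09; 0.07 and 0.15 on the 2 slides; adjusted p = 0.0132, and adjusted p = 0.581 with an estimated correlation). The P450 list no longer passed with no filter on dim probes (median 0.01, adjusted p = 0.0816). The UDP-glycosyltransferase median was 0.21 without atnaod 2. Pectin-modifying enzymes had 2 rises, with PME2 first, and 1 fall in 26, also over the list alone (median 0.15; 0.14 and 0.19 on the 2 slides; adjusted p = 0.0194, and adjusted p = 0.581 with an estimated correlation). They missed the threshold without wild type 2 (adjusted p = 0.0561), without atnaod 3 (0.0665) or once the inhibitor and receptor proteins that the keyword had taken in were left out (0.0638). F-box genes had 0 of 27 called with limma, 7 at an unadjusted p under 0.05, and a median of 0.13 (0.10 and 0.16 on the 2 slides; adjusted p = 0.0242, and adjusted p = 0.581 with an estimated correlation), with adjusted p = 0.0527 without atnaod 3, 0.0581 on the first slide alone and 0.0756 with array weights.

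Clock genes were slightly higher, with 17 of 21 above 0. RVE1 rose by 0.81 (SE 0.0993, adjusted p = 0.0199), the 1 gene called also adjusted over the list alone, and LHY, CCA1 and TOC1 stood at 0.69, 0.39 and 0.27 without a call (list median 0.19, and 0.12 without wild type 3; 0.09 and 0.26 on the 2 slides; adjusted p = 0.00703, and adjusted p = 0.605 with an estimated correlation). Genes of the rapid response to touch and wounding had a median of 0.32 (0.40 and 0.11 on the 2 slides) with 0 of 17 called with limma, 4 at an unadjusted p under 0.05, and ERF6 and WRKY40 at 0.49 and 1.14 (adjusted p = 0.0153, and adjusted p = 0.735 with an estimated correlation). In the wild-type samples the median of this list against the wild-type mean was -0.39, 0.36 and 0.12, and the list missed the threshold without wild type 1 (median 0.03, adjusted p = 0.348), without atnaod 1 (0.19, adjusted p = 0.0948) or with array weights (0.13, adjusted p = 0.170).

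Several lists were not past the threshold in the main setting. With limma 0 of 24 photosynthesis genes (median -0.02, adjusted p = 0.857), 0 of 11 floral organ identity genes (-0.03, adjusted p = 0.822) and 0 of 8 tapetum genes (-0.10, adjusted p = 0.940) were called, and 0, 0 and 3 had an unadjusted p under 0.05. The photosynthesis list passed with array weights (adjusted p = 0.0349). No seed storage gene passed the signal filter. In the senescence and abscission list (median 0.10, adjusted p = 0.0936) the abscission peptide gene IDA fell by 0.71 and DIN10 rose by 0.58, and the list passed without atnaod 2 (adjusted p = 0.00860) or with no filter on dim probes (0.0284). Salicylate-associated defence had 0 of 20 called with limma and 6 at an unadjusted p under 0.05 (list adjusted p = 0.875), but passed lower without atnaod 1 (median -0.32, adjusted p = 0.0265). The abscisic acid and cold list had 1 rise, GOLS3 at 2.30-fold, and 1 fall in 33 (adjusted p = 0.857), that of COR15B at -0.62, lost with slide as a block (adjusted p = 0.0505) or the replicate block (adjusted p = 0.0592). In the auxin list IAA5 fell by 1.05 (adjusted p = 0.0530 with the replicate block) and GH3.17 rose by 0.54 (adjusted p = 0.0362), and the list did not pass (adjusted p = 0.169). Expansins and xyloglucan enzymes had 6 falls, among them EXPB4 at -1.60 and XTH1 at -1.44, and 1 rise in 62 (adjusted p = 0.822).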

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

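Of the settings below, the normexp correction on the median signal, the first slide alone, the ornithine list without AtNAOD and the trimmed keyword lists were chosen only after the data were seen. The fall of AtNAOD stayed past its threshold under all 19 alternatives, between -8.94 and -1.23 on the log2 scale. The end at -1.23 came from the filter asking for signal on all 6 arrays, which left only the second probe. The 1414 calls became 243 with normexp (4 before 5 spots of extreme background were replaced), 12 with the deposited values, 22 with no filter on dim probes, 2259 with a trended and robust prior, 3977 with array weights, 2123 with slide and the identical 2123 with scan date as a block, and 13 on the first slide alone. Leaving out each sample gave 15 to 1551. Quantile normalization, median centring, the filter on all 6 arrays, the mean over probes and the replicate block kept the count within 1.5 times. Under the replicate block 1297 genes were called, 926 of them among the 1414; of 217 named genes 26 lost and 9 gained a call, and no list changed. No gene shared with the 1414 had the other sign under any alternative, and 7 of the 1414 were called in all 18 distinct alternatives. The 20 lists became 0 with an estimated correlation and 2 with fry, and 17 to 21 elsewhere. Fewer samples or a larger number of dim genes tested lie in the construction of some settings; for the others the cause was not tested. Normexp on the mean signal was not run. Dim signal limits the genes near background: 16 called genes were above background on no atnaod array and 39 on no wild-type array.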

Other observations

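The tests below of pistil share, flower age and DNA linked to the insertion, and of gene families, were chosen only after the results were seen. Among 420 families sharing a symbol stem, 4 held more falls past the adjusted threshold than the 206 falls in 8390 such genes would give, and none more rises (smallest adjusted p = 0.377). The LCR and H2A families overlap the cysteine-rich and histone lists. In the LCR family 25 of 51 members fell (one-sided Fisher exact test, adjusted p = 1.55e-24), the SCRL family of S-locus cysteine-rich-like proteins 7 of 14 (adjusted p = 6.05e-06) and the H2A histones 5 of 9 (adjusted p = 0.000277). Of 27 RALF-like peptide genes 6 fell (adjusted p = 0.00823; family median -0.13), among them RALFL3, above background in 2 of 3 atnaod samples, at -1.55 (SE 0.224), RALFL2 at -1.33, RALFL21 at -1.30 and RALFL7 at -1.26. Members of a family share sequence, so the test counts genes that are not independent. In the late embryogenesis abundant list, which did not pass (adjusted p = 0.149, and 0.0154 without wild type 1), LEA18 fell by 1.78 (SE 0.132, adjusted p = 0.00543) and GEA6, above background in 1 of 3 atnaod samples, by 1.30. The iron uptake gene IRT1 rose by 0.67 (adjusted p = 0.0392, 0.0523 with the replicate block), while the iron-deficiency regulator BHLH039 stood at -3.03 without a call (adjusted p = 0.0783, 0.0395 with the replicate block). In the glucosinolate list, which did not pass (adjusted p = 0.231), CYP79B2 rose by 0.65 and TGG2 by 0.51, the latter with adjusted p = 0.0542 under the replicate block.

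The 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. Of these, 1 split, the real one, gave as many limma calls (1414, with 6300 at an unadjusted p under 0.05), and the highest of the others gave 0, with at most 2282 unadjusted. The 4 splits that part all 3 replicate pairs include the real one, and the others of them gave 0, with at most 919 unadjusted.

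The called lower genes of the cysteine-rich, flavonoid, early seed, carpel and MADS-box lists, 38 in all, had a median change of -1.20, and against wild type -0.81, -1.22 and -1.50 in atnaod 1, 2 and 3. Both slides held both genotypes in equal numbers, and the medians of 10 of the 10 lower lists lay below 0 on each. A smaller share of pistil cannot be told apart from the genotype: the median of all 13 tested carpel, ovule and fruit genes, 0.0522 (SD 0.362), lay above that of all 138 tested members of the other 4 lists, -0.26, by less than that SD, and the 38 were picked for falling. Pollen markers stood at -0.18, 0.27 and 0.60 in atnaod 1, 2 and 3. Among the atnaod samples they were higher where the 38 fell further, as a smaller pistil share would have it. The wild-type samples did not show this. In wild type 1, 2 and 3 the pollen markers stood at -0.07, 0.01 and 0.05, and the 38 rose with them, at -0.15, 0.06 and 0.07. Over all tested members, falls also grew from atnaod 1 to 3 in the flavonoid (-0.11, -0.32 and -0.40) and early seed lists (-0.06, -0.53 and -0.58). No such growth was seen in the medians of the cysteine-rich (-0.45, -0.43 and -0.46), MADS-box (-0.17, -0.15 and -0.09) and carpel lists (0.03, -0.003 and 0.13). The cysteine-rich median takes in many genes that were not called. The called LCR genes, picked for falling, each fell further on the second slide, which held atnaod 3, than on the first. LCR84, for example, stood at -2.96 against -1.64. The tapetum median (8 of 25 members tested) and the floral organ identity median were -0.10 and -0.03, and neither list measures pistil share. Younger flowers in the atnaod harvest remain open, since the senescence and abscission median of 0.0981 lay within the list's SD of 0.368, so flower age cannot be told apart from the genotype. In both comparisons the SD is the spread of single genes and not the error of a median, so neither could easily have decided. A difference in ovule or seed development between the genotypes also stays open and was not tested.

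Besides AtNAOD, 6 called transcripts had a fitted change of at least 8-fold, all lower: MRD1, AT5G01080 (-5.65, above background in 1 of 3 atnaod samples), AT3G01345 (-4.20), AT5G03090 (-3.97, above background in 2 of 3), AT3G09990 (above background in none, at least 5.62-fold lower in the main setting) and AK229766 (-3.09), the last 5 chosen after their values were seen. The call of AT3G09990 was lost with normexp (-0.91) and with the deposited values (-1.06), that of AT5G01080 under the filter on all 6 arrays (-0.46), and that of AT5G03090 in 6 alternatives, while normexp left it at -2.00. DNA linked to the insertion was argued against: 0 of the 5 with a locus code lay among the neighbours of AtNAOD, and 11 of 186 neighbours were called, 5.91% against 6.04% elsewhere (one-sided Fisher exact p = 0.572). A sequence difference between the lines under single probes may account for some of them and cannot be told apart from lower transcript, because only 1 gene, AT5G01080, had another probe above background in wild type, at -0.46, so that 0 genes had a further probe lower by over 1. An effect of the genotype itself was not tested separately and stays open.

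The clock genes were higher in atnaod with a median of 0.19. Its medians were 0.09 and 0.26 on the 2 slides, each of which held both genotypes. A shift in the time of harvest cannot be told apart from the genotype: 8 morning genes had a median of 0.33 and 6 evening genes 0.09, and the difference of 0.238 was close to the list's SD of 0.246. The SE of 0.120 used beside it is that of a difference of means over genes taken as independent, which they are not. An effect of genotype on the clock was not tested and stays open. All 46 lists, this one included, missed the threshold with an estimated correlation.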
